A study of Physcomitrium patens with 12 samples.

How the data were processed

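RNA was sequenced from mature gametangia, the sexual organs of the moss Physcomitrium patens, strain Gransden, collected on day 18 of sporophyte induction. Each of the 12 libraries was made from 8 antheridia or 8 archegonia of wild type or of the PpPINC mutant line pinC#29, with 3 libraries for each of the 4 groups of genotype and organ. Per the labels' protocols, the organs were picked with forceps into TRIzol, the RNA was purified with a Direct-zol microprep kit, and cDNA was made by Smart-seq2, a full-length method for very small RNA amounts that does not mark strand and carries no molecular identifiers. The groups and the replicate numbers were taken from the sample titles. The organs were collected on 3 occasions, and the labels do not say which libraries share an occasion. The titles call the libraries biological replicates, and nothing says whether the plants came from separate cultures, so p-values measure the spread between these libraries.

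The authors deposited a table of whole-number read counts for 32926 genes in the 12 libraries, and 6 tables of their own DESeq2 comparisons. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.6 and cutadapt 2.10 and aligned with HISAT2 2.1.0, and DESeq2 2.11.40.6 was run. The genome build, the annotation and the settings of the read counting are not given in the sources used here. The name of the deposited count table refers to counting over coding sequence. The authors' deposited comparison tables hold log2 fold changes, p-values and adjusted p-values without a header. In these tables the adjusted values were checked to be the Benjamini-Hochberg adjustment of the p-values, and the sign of the log2 fold change was checked against the counts.

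Gene identifiers of the count table were looked up in a RefSeq gene table of the assembly ASM5946719v1. Of its 27567 genes, 0 matched, and the files do not pair identifiers with names, so genes are given by identifier and without a function. The gene lists, product families and cell type markers that had been fixed for testing rest on product descriptions and were not tested. Because reads of overlapping genes and of near-identical copies cannot be told apart without the annotation, the level of any single gene may include reads of another.

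The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM scaling factors, robust estimation and the non-legacy fit. In this version the non-legacy fit is not the default and was set explicitly. Low-count genes were removed with filterByExpr on the group, which left 22792 genes; 5037 of the 32926 had no count in any library. A single fit of the 4 group means over all 12 libraries gave the comparisons of genotype within each organ, of organ within each genotype, the averages of each over the other factor, and the interaction, which is the genotype difference in antheridia minus that in archegonia. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no minimum fold change. The standard errors given are the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM, counts scaled to the TMM-adjusted library total, and principal components used log2 CPM with a prior count of 2.

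Named genes followed a rule fixed before the data were examined. For genes without a description, at most 2 higher and 2 lower genes per comparison were taken, with the largest fitted change among called genes whose libraries did not overlap between the groups and whose mean was at least 10 CPM in the higher group. Where no gene was called, those with the smallest p were taken. Other genes named are said to have been chosen after their values were seen. The locus Pp3c10_24880 had been written down beforehand, from memory of the literature, as that of PpPINC, to be used only if the reference described it as an auxin efflux carrier. The reference did not, so which gene was targeted is left open, and the locus is reported as a candidate.

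Total counts ranged from 19038033 to 39833129 per library. A floor of 3 counts, the upper limit that a count of 0 allows, was between 0.0881 and 0.142 CPM in a single library. Where a group had no count, folds were computed against 3 counts over the whole group. Where it had 1 to 3 counts, and for Pp3c11_4360 with 4 counts in wild type archegonia, an exact Poisson interval at the 95% level is given. Such floors and intervals cover counting error only, since amplified reads are not independent molecules. No pair of replicates agreed within sampling noise, the lowest chi-square per degree of freedom being 108.

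The test was tried on simulated data, in which 200 of 22792 genes were changed in the mutant, 100 of them 2-fold and 100 of them 8-fold. Every group was simulated with the same spread for each gene, whereas the real groups differed in spread. For mutant against wild type in antheridia it called 0% of the genes changed 2-fold and 27% of those changed 8-fold, with 6 unchanged genes called. For mutant against wild type in archegonia it called 0% and 11%, with 1 unchanged gene called.

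The alternatives, set before the data were examined, were DESeq2 size factors, upper-quartile factors, no low-count filter, a filter of at least 10 counts in 6 libraries, the DESeq2 1.42.0 Wald test, the legacy edgeR fit, limma 3.58.1 voom with sample quality weights, the replicate number as a block, fits of only the groups compared, a log2 fold change of at least 1, and each library left out in turn. A fit without the 3 libraries with the fewest detected genes was added after seeing the data. For a check of archegonial RNA in wild type antheridia, also added, 30 archegonium markers were taken from the mutant libraries: the genes called lower in antheridia, at under 10% of their archegonium mean there, with the highest archegonium means. A second list of 30 was taken from the wild type libraries in the same way and read in mutant antheridia. Figures were drawn with matplotlib 3.10.9.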

Results

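Transcript levels were measured by RNA-seq in mature antheridia, the male organs that release swimming sperm, and mature archegonia, the female organs that each hold an egg, of Physcomitrium patens. Wild type plants and the PpPINC mutant line pinC#29 were compared, with 3 libraries of 8 pooled organs in each of the 4 groups. All mutant libraries came from this single line, so effects of the mutation cannot be told apart from other differences of the line. PIN proteins export the hormone auxin from plant cells, and the series title places the study in spermatogenesis and sporophyte abortion. Total counts were between 19038033 and 39833129 per library. Genes with at least 1 count numbered between 21654 and 24802 in 9 libraries, but 19088 and 20359 in mutant antheridia 2 and 3 and 19803 in mutant archegonia 3. These libraries were not the shallowest, with 25464700, 39833129 and 30939475 counts. Rank correlations across genes between libraries of a group were 0.823 to 0.965 in archegonia and 0.739 to 0.921 in antheridia. Organ separated the libraries along the first principal component, which held 35.8% of the variance, and genotype did not.

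**Figure D1:**
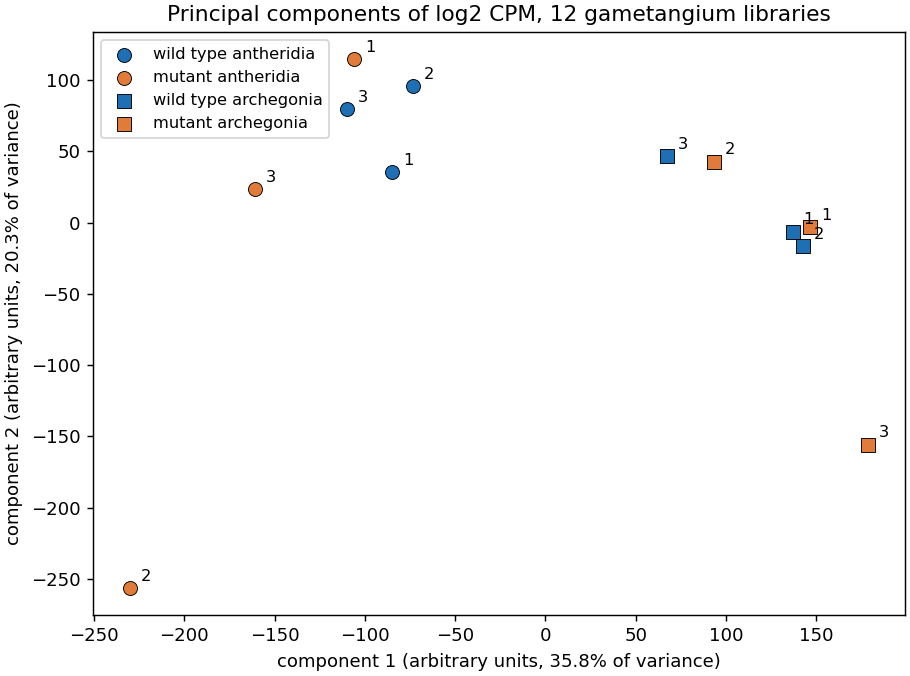
Principal components 1 (35.8% of variance) and 2 (20.3%) of log2 CPM, in arbitrary units, with a point for each of the 12 libraries and the replicate number beside it. All 6 antheridium libraries (circles) lie on the negative side of component 1 and all 6 archegonium libraries (squares) on the positive side, while mutant antheridia 2 and mutant archegonia 3 stand apart along component 2.

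The candidate for the targeted gene, Pp3c10_24880, had 94, 38 and 56 counts in wild type archegonia and 3, 2 and 0 counts in mutant archegonia, or 2.50 ± 1.57 against 0.0724 ± 0.0698 CPM (SD, n = 3). Wild type antheridia had 66, 39 and 165 counts. Among antheridia labelled mutant, replicates 2 and 3 had 0 counts, but the library labelled mutant antheridia 1 had 66 counts, or 2.93 CPM, within the wild type range of 1.51 to 6.68 CPM. The fitted log2 fold change was -5.17 ± 1.78 (SE) in archegonia, with an edgeR adjusted p of 1, and -1.99 ± 1.19 in antheridia, with an edgeR adjusted p of 0.671. Neither passed the threshold. Without mutant antheridia 1 the mutant antheridia had no count, at least 68.2-fold lower against 3 counts over both libraries, with an edgeR adjusted p of 0.0788. The files and the reference do not pair this identifier with a name, so it checks the labels only as far as the candidate is right. Directions for mutant antheridia below rest in part on the library labelled mutant antheridia 1.

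Mutant and wild type antheridia were compared to ask how the male organ of the PpPINC mutant line differs from that of wild type. Only 3 genes passed the threshold in edgeR, and all 3 were lower in the mutant. Pp3c3_11110 averaged 75.1 ± 13.3 CPM in wild type and 5.70 ± 2.46 CPM in mutant antheridia (SD, n = 3), a log2 fold change of -3.73 ± 0.45 (SE; edgeR adjusted p = 0.0363). The others were chosen after their values were seen, since they fell outside the naming rule. Pp3c21_8410 averaged 7.43 ± 2.92 CPM in wild type and 0.162 ± 0.103 CPM in the mutant, a log2 fold change of -5.45 ± 0.81 (SE; edgeR adjusted p = 0.0455). Pp3c4_19980 averaged 3.71 ± 1.31 CPM in wild type and had no count in the 3 mutant libraries, at least 96.2-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.0455). All 3 genes were lower in each mutant library than in every wild type library. The authors' deposited table called 15 genes in this comparison, 5 of them higher and 10 lower in the mutant, among them Pp3c3_11110 with a log2 fold change of -3.08 and Pp3c21_8410 with -3.25, while Pp3c4_19980, at -2.10 with an adjusted p of 0.174 in that table, was not called there. For these 3 genes the DESeq2 Wald test here gave larger changes, -3.69, -5.48 and -8.97, so fold sizes are not compared with that table. The smallest adjusted p in the authors' deposited table, 1.63e-14, belonged to Pp3c12_11710, at a log2 fold change of -4.87, and edgeR's adjusted p for this gene was 0.0538. It was the most abundant of 30 archegonium markers chosen from the mutant libraries, whose median level in wild type antheridia 1, 2 and 3 was 21.0%, 10.7% and 10.8% of that in wild type archegonia. The lowest of these markers stood at 0.255%, 0% and 1.49% in the same libraries. The medians are thus not a share of archegonial RNA common to all genes. For 30 markers chosen from the wild type libraries, 8 of them on both lists, the medians in mutant antheridia 1, 2 and 3 were 2.34%, 0.143% and 0.562%. Each list was chosen for low levels in the antheridia of its own genotype, so these medians do not compare 1 set of genes between the genotypes. On the same scale wild type antheridia had 8.72% for Pp3c12_11710, or 5.11% without wild type antheridia 1, 28.1% for Pp3c3_11110, 102.6% for Pp3c21_8410 and 1227% for Pp3c4_19980. The DESeq2 Wald test over 12 libraries called 239 genes, 74 of them higher in the mutant and 165 lower. The legacy edgeR fit, limma-voom and the fit of only the groups compared each called 0. In the fit of only the groups compared, the edgeR adjusted p of Pp3c3_11110, Pp3c21_8410 and Pp3c4_19980 was 0.705, 0.958 and 0.958. The main fit shares 1 spread per gene over all 4 groups, so its calls rest partly on replicates outside this comparison. Replicate pairs had a chi-square per degree of freedom of 535 to 647 in mutant antheridia and 196 to 205 in wild type antheridia. In archegonia it was 112 to 218 in wild type and 108 to 543 in the mutant. Without a low-count filter Pp3c21_8410 and Pp3c4_19980 lost their call, at edgeR adjusted p of 0.0542 and 0.0899. They also lost it with the replicate number as a block, at 0.163 each. Without mutant antheridia 1, which leaves the mutant libraries with 19088 and 20359 detected genes, edgeR called 159 genes, 150 of them lower and all 3 named genes among them. Without mutant antheridia 2 it called 1 gene, which was none of these 3, and without any other single library it called 0.

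Mutant and wild type archegonia were compared to ask the same of the female organ. No gene passed the threshold in edgeR, where 257 of 22792 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.448. These 257 are 1.13% of the genes, fewer than a calibrated test gives at 0.05 when no gene differs. The edgeR test thus appears conservative here, and its count of 0 does not show that the mutation had no effect. Its spread for each gene is shared with the antheridia, so its p-values do not measure the spread among archegonia only. From the archegonium libraries alone, edgeR had 554 genes with an unadjusted p under 0.05 and again called 0. With limma-voom and quality weights 2440 genes had an unadjusted p under 0.05. The clearest gaps between the groups were in genes that missed the threshold. Pp3c6_26100 averaged 47.3 ± 2.75 CPM in wild type archegonia (SD, n = 3) and had no count in the 3 mutant libraries, at least 1250-fold lower over the group, with an edgeR adjusted p of 0.948. The same gene averaged 40.8 ± 13.5 CPM in wild type antheridia and had 0, 102 and 1 counts in mutant antheridia 1, 2 and 3. These counts enter the shared spread, and in the fit of archegonia alone the edgeR adjusted p of Pp3c6_26100 was 0.053. Pp3c7_8820 averaged 78.3 ± 63.9 CPM in wild type archegonia and 3.39 ± 1.62 CPM in mutant archegonia, a log2 fold change of -4.54 ± 0.69 (SE; edgeR adjusted p = 0.448), or -3.63 without wild type archegonia 3, at 151.3 CPM. Pp3c11_4360 had 0, 0 and 4 counts in wild type archegonia and 154, 241 and 220 counts in mutant archegonia, a log2 fold change of 7.17 ± 1.32 (SE; edgeR adjusted p = 1). The ratio of the means was 158.8, with a counting interval of 62.0 to 583, and without wild type archegonia 3, which held the 4 counts, at least 143.8. In antheridia this gene had no count in the 3 wild type libraries and 33, 133 and 90 counts in the mutant, at least 84.3-fold higher over the group, or 50.1-fold without mutant antheridia 2. Pp3c25_9710 averaged 0.0954 ± 0.0765 CPM in wild type and 36.6 ± 49.2 CPM in mutant archegonia, a log2 fold change of 8.64 ± 1.55 (SE; edgeR adjusted p = 1), with 93.1 CPM in mutant archegonia 3 and a mean of 8.37 CPM in the others. The log2 fold change of Pp3c25_9710 was 6.50 without mutant archegonia 3 and 9.36 without wild type archegonia 1. The authors' deposited table called 12 genes here, 8 higher and 4 lower in the mutant, and these 4 genes were among them. In the authors' deposited table Pp3c6_26100 had a log2 fold change of -6.56 with an adjusted p of 1.53e-66, and Pp3c11_4360 had 3.29 with an adjusted p of 5.88e-11. For these genes the DESeq2 Wald test here gave larger log2 fold changes, -12.66 and 7.33, so fold sizes are not compared with the authors' table. The DESeq2 Wald test over 12 libraries called 10 genes, these 4 among them, limma-voom called 4, with Pp3c6_26100 and Pp3c11_4360 among them, and the legacy edgeR fit 0. Without mutant antheridia 2 edgeR called 1 gene, Pp3c6_26100, with an edgeR adjusted p of 0.00262, where its adjusted p over the alternatives ranged from 5.10e-07 in the DESeq2 Wald test to 1 in edgeR.

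**Figure D2:**
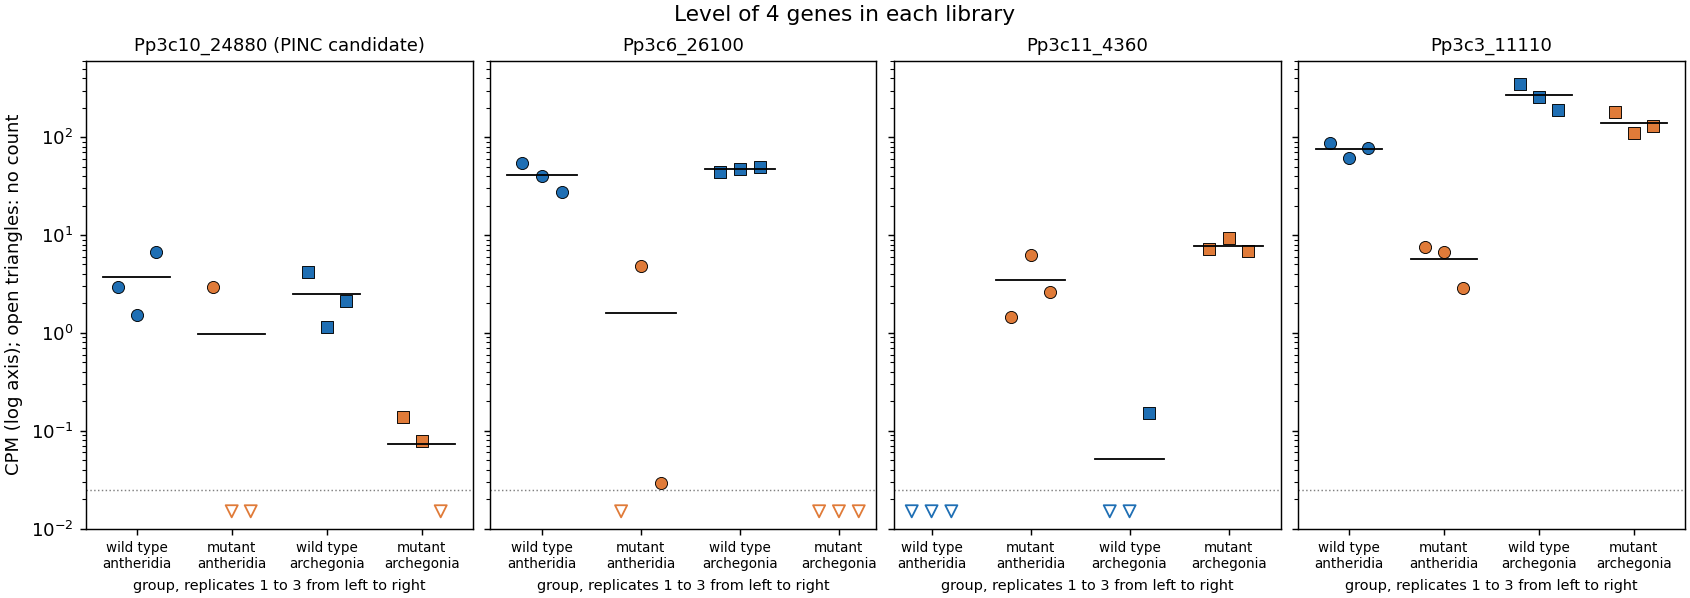
Level of 4 genes in CPM, on a log axis, with a point for each library of the 4 groups and a line at the mean of 3 libraries; open triangles under the dotted line mark libraries without a count. Pp3c6_26100 had no count in 3 of 3 mutant archegonium libraries, Pp3c11_4360 had none in 3 of 3 wild type antheridium libraries, and the library labelled mutant antheridia 1 had 2.93 CPM of the candidate Pp3c10_24880.

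The interaction asked whether the difference between the mutant line and wild type was unlike in the male and female organs. No gene passed the threshold in edgeR, with 961 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.610. Pp3c7_8820 averaged 764 ± 105 CPM in wild type and 1622 ± 584 CPM in mutant antheridia (SD, n = 3), against the lower level in mutant archegonia given above, an interaction of 5.62 ± 0.89 on the log2 scale (SE; edgeR adjusted p = 0.610), or 4.72 without wild type archegonia 3. Pp3c11_26120 averaged 53.5 ± 29.3 CPM in wild type and 177.7 ± 104.7 CPM in mutant antheridia, and 4.69 ± 1.69 CPM in wild type and 0.795 ± 0.388 CPM in mutant archegonia (edgeR adjusted p = 0.811). Pp3c12_11710, the archegonium marker named above, averaged 1721 ± 1407 CPM in wild type and 7.49 ± 2.52 CPM in mutant antheridia, and 19750 ± 8855 CPM in wild type and 8372 ± 2263 CPM in mutant archegonia, an interaction of -6.61 ± 1.27 (SE; edgeR adjusted p = 0.850), or -5.83 without wild type antheridia 1, at 3144 CPM. Pp3c21_8410 was at 7.24 ± 1.36 CPM in wild type and 7.04 ± 0.73 CPM in mutant archegonia, so that the gap seen in antheridia gave an interaction of -5.41 ± 1.00 (SE; edgeR adjusted p = 0.610). Across the 22792 genes, which are not independent replicates, the genotype differences of both organs had a Spearman correlation of -0.033 and a Pearson correlation of 0.013. The DESeq2 Wald test called 61 genes, these 4 among them, and limma-voom and the legacy edgeR fit 0. Without mutant antheridia 1 edgeR called 16 genes, 15 of them with a negative interaction, and of the 4 named genes only Pp3c7_8820, at 5.79 with an edgeR adjusted p of 0.0488. Over the alternatives its adjusted p ranged from 5.67e-07 in the DESeq2 Wald test to 1 in edgeR.

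Antheridia and archegonia of wild type were compared to describe the difference between the organs. In edgeR 672 of 22792 genes were called, 583 of them higher in antheridia and 89 higher in archegonia, with a median absolute log2 fold change of 4.58. Pp3c11_9530 averaged 99.2 ± 60 CPM in wild type antheridia (SD, n = 3) and had no count in 3 archegonium libraries, at least 2700-fold higher over the group (edgeR adjusted p = 0.00031). Pp3c6_26330 averaged 54.6 ± 25.2 CPM in wild type antheridia and had no count in archegonia, at least 1490-fold higher (edgeR adjusted p = 0.00179). On the archegonial side, Pp3c2_13210 averaged 10.2 ± 3.59 CPM in archegonia against a single count over 3 antheridium libraries, a ratio of 745 with a counting interval of 134 to 29400 (edgeR adjusted p = 0.00957), or at least 160.5 without wild type antheridia 2, which held that count. Pp3c15_5450 averaged 17.9 ± 16.4 CPM in archegonia against 3 counts in antheridia, a ratio of 436 with a counting interval of 149 to 2110 (edgeR adjusted p = 0.00738), and without wild type archegonia 3, at 36.5 CPM, the mean was 8.56 CPM and the ratio 208.8. Wild type antheridia 2 held these 3 counts as well, and without it the ratio was at least 281.8. The authors' deposited table called 2987 genes in this comparison, 2022 higher and 965 lower in antheridia, and held 661 of the 672. The count was 1366 with the DESeq2 Wald test, 3050 with limma-voom, 343 with the legacy edgeR fit and 1658 from the 6 wild type libraries alone. Of these 76.9%, 69.7%, 88.0% and 72.6% were higher in antheridia, against 86.8% of the 672. Without wild type antheridia 2 or 3 it was 397 or 289, without wild type archegonia 1 or 2 it was 211 or 208, and without the 3 libraries with the fewest detected genes, an alternative chosen after seeing the data, it was 2271. With single libraries left out, the 89 genes higher in archegonia became 15 without wild type archegonia 1 and 147 without mutant antheridia 3, the lowest and highest values.

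The same organ comparison was made within the mutant. In edgeR 1841 genes were called, 1537 higher in antheridia and 304 higher in archegonia, with a median absolute log2 fold change of 4.97. This is more than the 672 of wild type, but the order depended on the test. It was reversed with limma-voom, at 1421 against 3050 in wild type, and in fits of each genotype alone, at 575 against 1658. The authors' deposited tables also had fewer in the mutant, 1749 against 2987. The DESeq2 Wald test and the legacy edgeR fit kept the order. The counts thus do not show which genotype had the larger organ difference. Pp3c10_14830 averaged 93.5 ± 81.1 CPM in mutant antheridia (SD, n = 3) and had no count in mutant archegonia, at least 2480-fold higher over the group (edgeR adjusted p = 0.000319). Pp3c3_33100 averaged 89.2 ± 89.9 CPM in mutant antheridia and also had no count in mutant archegonia, at least 2360-fold higher (edgeR adjusted p = 0.000932). Both were highest in mutant antheridia 2, without which these bounds were 1358-fold and 1057-fold. Pp3c25_9710 averaged 36.6 ± 49.2 CPM in mutant archegonia and had no count in mutant antheridia, at least 950-fold higher in archegonia (edgeR adjusted p = 0.00453), or 217-fold without mutant archegonia 3. Pp3c6_18329 averaged 22.8 ± 37.0 CPM in mutant archegonia and had no count in mutant antheridia, at least 593-fold higher in archegonia, with an edgeR adjusted p of 0.0448 that rose above the threshold in 14 of 23 alternatives. This gene was at 65.5 CPM in mutant archegonia 3 and averaged 1.497 CPM in the others, which gives at least 38.8-fold and is under the 10 CPM set for naming a gene. Of the 583 genes higher in wild type antheridia, 555 (95.2%) were also called higher in mutant antheridia, where independent lists would share 39.3. Of the 89 genes higher in wild type archegonia, 57 (64.0%) were also called in the mutant, where independent lists would share 1.19, and 0 genes were called in opposite directions. These comparisons share no library but come from 1 fit with a shared spread for each gene. This can raise the overlap above that of independent lists, so the numbers for independent lists are not a test. The organ differences of wild type and mutant had a Spearman correlation of 0.505 and a Pearson correlation of 0.701 across genes, which are not independent replicates. The authors' deposited table called 1749 genes in the mutant, 1449 higher and 300 lower in antheridia, and held 1498 of the 1841. The count was 2848 with the DESeq2 Wald test, 951 with the legacy edgeR fit, 1421 with limma-voom, of which 1332 were higher in antheridia and 89 in archegonia, and 575 from the 6 mutant libraries alone. The DESeq2 Wald test, the legacy fit and the 6 libraries alone had 75.2%, 84.1% and 93.7% of their calls higher in antheridia, against 83.5% of the 1841. It was 843 without mutant archegonia 1 and 1096 without mutant archegonia 3, the library of this group with the fewest detected genes, while without mutant antheridia 1 it was 2223, 1363 higher in antheridia and 860 higher in archegonia.

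**Figure D3:**
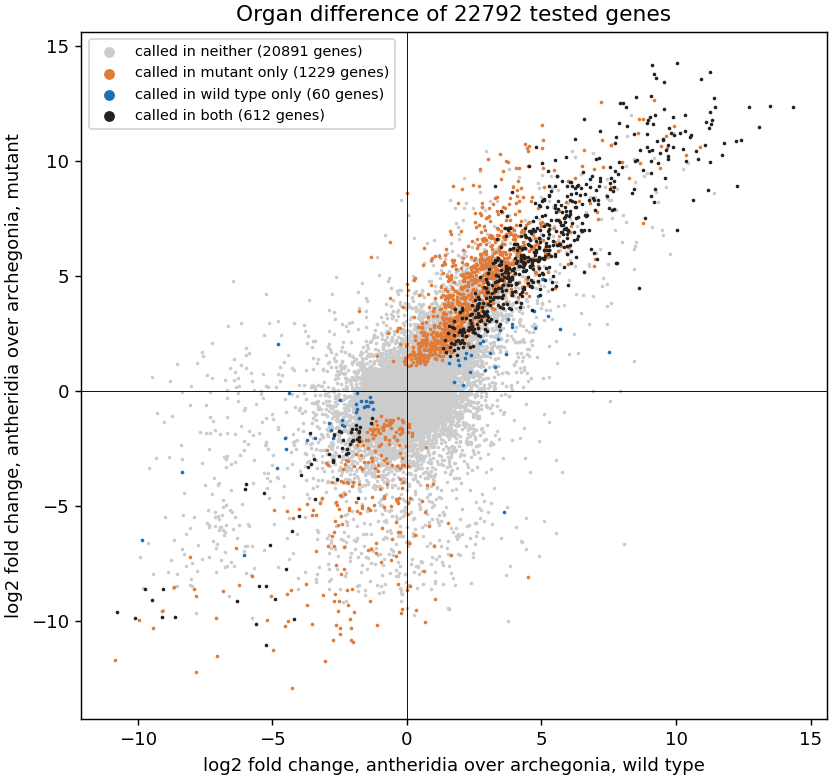
Log2 fold change of antheridia over archegonia in wild type (x axis) and in the mutant (y axis), with a point for each of 22792 tested genes, colored by whether edgeR called it. The 612 genes called in both genotypes all have the same sign in both, and 555 of them are higher in antheridia.

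Averaged over both organs, mutant and wild type did not differ at the threshold in any gene in edgeR, with 1131 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0688. That value belonged to Pp3c3_11110, whose averaged log2 fold change was -2.33 ± 0.30 (SE), and which was at 267 ± 81.7 CPM in wild type and 140.6 ± 36.8 CPM in mutant archegonia (SD, n = 3). Pp3c12_11710 had an averaged log2 fold change of -4.54 ± 0.67 (SE; edgeR adjusted p = 0.0982). Pp3c11_4360 had an edgeR adjusted p of 0.0982, with counts in 6 of 6 mutant libraries and in 1 of 6 wild type libraries, and no averaged fold is given because wild type antheridia had no count. Pp3c26_3990 averaged 3.83 ± 0.31 CPM in wild type and 29.6 ± 5.23 CPM in mutant antheridia, and 7.35 ± 1.46 CPM in wild type and 25.6 ± 13.7 CPM in mutant archegonia, an averaged log2 fold change of 2.37 ± 0.36 (SE; edgeR adjusted p = 0.0982). The authors' deposited table called 0 genes as well. Its log2 fold changes were -0.40 for Pp3c12_11710 and -0.62 for Pp3c3_11110, against -4.54 and -2.33 in edgeR. The tests are therefore not alike, and the counts of 0 are not taken to agree. The DESeq2 Wald test called 92 genes, the 4 named genes among them, limma-voom 2, with Pp3c11_4360 among them, and the legacy edgeR fit 0. Without mutant antheridia 1 edgeR called 53 genes, 2 higher and 51 lower in the mutant, and the 4 named genes passed, with edgeR adjusted p between 0.0132 for Pp3c3_11110 and 0.0418 for Pp3c26_3990. Without mutant archegonia 3 it called Pp3c26_3990 alone, and without mutant antheridia 2 it called 1 gene, none of these 4. Over the alternatives the adjusted p of the 4 genes ranged from 2.63e-15 in the DESeq2 Wald test to 0.748 in the legacy edgeR fit.

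Averaged over both genotypes, antheridia and archegonia differed in 3035 genes in edgeR, 2364 higher in antheridia and 671 higher in archegonia, with a median absolute log2 fold change of 3.46. Pp3c11_9530 averaged 129.5 CPM over the 6 antheridium libraries against 2 counts over the 6 archegonium libraries, a ratio of 10400 with a counting interval of 2890 to 86100 (edgeR adjusted p = 6.15e-06), or at least 6021 without mutant archegonia 1, which held both counts. Pp3c6_26330 averaged 75.1 CPM in antheridia against a single count in archegonia, a ratio of 12100 with a counting interval of 2169.5 to 477000 (edgeR adjusted p = 4.24e-05), or at least 3388 without mutant archegonia 2. Pp3c11_7340 averaged 12.3 CPM in archegonia with no count in antheridia, at least 617-fold higher in archegonia (edgeR adjusted p = 0.00682), or 331-fold without mutant archegonia 3, at 40.7 CPM. Pp3c6_18329 averaged 13.5 CPM in archegonia against a single count in antheridia, a ratio of 2040 with a counting interval of 366 to 80600 (edgeR adjusted p = 0.0135), but the 5 libraries other than mutant archegonia 3 averaged 3.11 CPM, a ratio of 470. With wild type antheridia 3 left out instead, which held the single count, the ratio was at least 569. The authors' deposited table called 3707 genes, 2758 higher and 949 lower in antheridia, and held 2828 of the 3035. The count was 1901 with the legacy edgeR fit and 1995 without wild type archegonia 1. Without mutant antheridia 1 it was 3437, with 2071 genes higher in antheridia and 1366 higher in archegonia.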

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

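The fit without the 3 libraries with the fewest detected genes was chosen after seeing the data, and it leaves a lone mutant antheridium library that is assumed to vary like the other groups. The planned gene list, product family and cell type marker alternatives were not run, because no description was available for the identifiers, and the single-group fit applies only to comparisons of 2 groups. DESeq2 size factors, upper-quartile factors, no low-count filter, the stricter filter and a log2 fold change of at least 1 kept every count of called genes within 1.5 times of the main one, but of the 3 genes called for the mutant in antheridia, 1 was among the 2 called without a filter and 2 were called with the stricter filter. Upper-quartile factors moved the median log2 fold change of all genes from -0.02 to -0.15 for the organs in the mutant and to -0.12 for the organs over both genotypes. With the DESeq2 Wald test the counts for mutant against wild type were 239 in antheridia, 10 in archegonia, 61 in the interaction and 92 over both organs, and for the organs 1366 in wild type and 2848 in the mutant. The legacy edgeR fit gave 0 for the mutant in antheridia and, for the organs, 343 in wild type, 951 in the mutant and 1901 over both genotypes. With limma-voom and quality weights, the mutant comparison gave 0 in antheridia, 4 in archegonia and 2 over both organs, and the organs of wild type gave 3050; the quality weights ranged from 0.190 for mutant archegonia 3 to 4.81 for mutant archegonia 1. Fits of only the groups compared gave 0 for the mutant in antheridia, 1658 for the organs in wild type and 575 in the mutant. Without the 3 libraries with the fewest detected genes, counts were 1 for the mutant in archegonia, 2 over both organs and 2271 for the organs in wild type, and 2 for the mutant in antheridia, none of which was among the 3 genes called with all libraries. With single libraries left out, counts for the mutant ranged from 0 to 159 in antheridia, 0 to 1 in archegonia, 0 to 16 in the interaction and 0 to 53 over both organs, the highest of each but archegonia being without mutant antheridia 1. For the organs they ranged from 208 to 925 in wild type, 843 to 2223 in the mutant and 1995 to 3437 over both genotypes. The candidate Pp3c10_24880 ranged from -9.58 to -1.26 in antheridia and from -5.97 to -4.47 in archegonia, the fitted -9.58 being against mutant libraries with no count, where a floor of 3 counts gives at least 68.2-fold, and missed the threshold each time, as it did under every other alternative. Apart from fewer libraries or another variance model, the cause of these shifts was not tested. With the replicate number as a block, the mutant comparison in antheridia gave 1 gene, Pp3c3_11110, with Pp3c21_8410 and Pp3c4_19980 each at an edgeR adjusted p of 0.163, and the organs of the mutant 1209, and the other counts stayed within 1.5 times. Of 12 pairs of libraries with the same number, 3 had deviations from their group means that correlated above 0.1, within a range of -0.42 to 0.18, and 5 correlated more with the same number than with the others, so the numbers are not taken to pair libraries. For the named genes, 516 of the values under alternatives kept their side of the threshold, 66 lost it, 24 gained it and 0 changed sign. The 3 genes called in antheridia lost their call under 15 to 17 alternatives each, and Pp3c25_9710 and Pp3c2_13210 lost theirs for the organs under 2 and 1. The simulated data had these library sizes and the same spread in every group. In them the main fit recovered no gene changed 2-fold between mutant and wild type. Changes of that size were thus not detectable by that fit under equal spread, and the other tests were not tried on these data.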

Other observations

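All tests in this part were set down only after the results they bear on had been seen. Few genes were restricted to an organ in both genotypes: 6 genes had at least 1 CPM in each of the 6 antheridium libraries and no count in archegonia, and 6 had at least 1 CPM in each of the 6 archegonium libraries and no count in antheridia.

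Genes higher in antheridia had consecutive identifiers more often than shuffled orders gave: in wild type 57 neighbouring pairs were both called, against a mean of 11.3 and a highest value of 27 in 1000 shuffled orders of the tested genes, and in the mutant 234 against at most 105, which argues against a random order. Genes higher in archegonia had 18 such pairs in the mutant against at most 10, and 44 over both genotypes against at most 30, while their 3 pairs in wild type equalled the highest shuffled value. Overlapping neighbours could share reads. In the mutant 120, 110 and 104 pairs of genes higher in antheridia were 2, 3 and 4 places apart, slightly above the highest shuffled values of 108, 104 and 101. Over both genotypes such pairs numbered 244, 233 and 222, against at most 220, 215 and 222. Genes higher in mutant archegonia had 10, 5 and 7 pairs at these distances, against at most 8, 10 and 9. No gene positions or sequences were used, and near-identical copies could share reads at these distances, so shared reads stay open as a cause. In wild type 21, 16 and 10 pairs were at these distances, with highest shuffled values of 21, 23 and 23, so that shared reads cannot be told apart from other causes in this shorter list of 583 genes. Whether such neighbours are related copies was not tested, since no sequence was used, and the hypothesis of groups of neighbouring genes with a shared organ pattern stays open.

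Without mutant antheridia 1, 150 genes were lower in mutant antheridia, with a median of 0 CPM in mutant antheridia 2 and 0.0147 CPM in mutant antheridia 3, but 8.37 CPM in mutant antheridia 1, which had no part in choosing them, and 9.24 to 12.7 CPM in wild type antheridia. Whether archegonial RNA in wild type antheridia contributed cannot be decided from the levels. The lower quartile of the 150 genes' level in wild type antheridia was 61.7% of that in wild type archegonia. High levels in wild type antheridia helped to choose these genes, which can raise this share. The 30 archegonium markers chosen from mutant libraries had lower medians, 10.7% to 21.0%. In each wild type antheridium library, however, the highest of these markers stood above 61.7%. Of these markers, 24 had a count in every antheridium library. The most abundant of them averaged 19750 CPM in wild type archegonia and 1721 CPM in wild type antheridia. Without wild type antheridia 1 the latter was 1010 CPM. A different list of 30 markers chosen from wild type libraries had medians of 0.143% to 2.34% in mutant antheridia. Independent loss of scarce transcripts could contribute to the pattern, but it was checked in a wider set of genes and not in the 150 themselves. In that set it left part of the overlap unexplained. Of 5939 genes at 5 to 20 CPM in the other antheridium libraries, 993 had no count in mutant antheridia 2 and 521 none in mutant antheridia 3. Among them 168 had none in both, against 113.3 for independent losses and 521 if the same genes were lost. Mutant archegonia 3 showed the like, with no count in 11.4% of these genes, where the other 5 archegonium libraries had 0.690% to 2.42%. As a control, 5784 genes at 5 to 20 CPM in the remaining libraries were used. Mutant archegonia 3 shared 143 genes without a count with mutant antheridia 2, against 123.0 for independent losses. With mutant antheridia 3 it shared 80, against 68.9. Both excesses were smaller than that of 168 against 113.3 between mutant antheridia 2 and 3. The mutation cannot be told apart from loss for the excess over 113.3, since a single mutant library at 8.37 CPM, slightly under the wild type range, is too few to decide.

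The candidate Pp3c10_24880 stood at 2.93 CPM in the library labelled mutant antheridia 1, 79.1% of the wild type mean. A mislabelled wild type library is argued against by Pp3c6_26100, which had 0 counts there and 680 to 1233 counts in wild type antheridia, and by the 33 counts of Pp3c11_4360, which had no count in wild type antheridia. Wild type RNA in the library would call for 32.3 CPM of Pp3c6_26100, where a count of 0 allows at most 0.133 CPM. Loss of scarce transcripts in mutant antheridia 2 and 3 cannot be told apart from the mutation as the source of their counts of 0, because 14.3% of genes at 1.85 to 7.40 CPM in wild type antheridia had no count in both, and a single gene is too few to decide. That the locus is not the targeted gene, or that the mutation leaves its transcript in place in some antheridia, stays open and was not tested.

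Other splits of the libraries were counted for each comparison. The 3035 genes of antheridia against archegonia over both genotypes were reached by 1 of 100 splits within the genotypes, the real one, with 568 as the highest of the others. A share of 1 in 100 is the smallest that these splits can give, so chance is argued against but not excluded. For the averaged genotype difference and the interaction, with 0 genes each, the highest of the other splits was 1, but every split, 100 of 100, gives at least 0 genes, so this count decides nothing about chance. The comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. Among these, the real value and the highest of the other splits were 3 and 0 for the mutant in antheridia, 0 and 0 in archegonia, 672 and 0 for the organs in wild type, and 1841 and 88 for the organs in the mutant.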
